A study of Mus musculus with 9 samples.

How the data were processed

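Bulk poly(A) RNA sequencing covered 9 mouse libraries in 4 groups: WT cultures (2), KO cultures (2), WT tumours (3) and KO tumours (2). The labels call the replicates biological, and their batch tag is the same as the setting, culture or tumour, so the effect of the knockout was taken within each setting. Per the labels' protocols, cultured cells were harvested near confluence, tumours were dissociated with enzymes before RNA extraction, ERCC control RNA was added, libraries carried unique molecular identifiers, and duplicates were removed by them. Per the submitters' processing notes, the tools were fastp 0.23.1, STAR 2.5.2b, featureCounts, Subread 1.5.2 and DESeq2, on GRCm38, with no role or order given. The annotation release, the strand setting and the treatment of reads with several positions are not given in the sources used here.

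The deposited count tables, 1 per setting, hold raw counts per Ensembl gene that the authors made with those tools, and all tests start from them. The deposited normalized tables hold a signal per gene that equals the raw count divided by 1 size factor per library. They list 13296 genes for culture, the smallest with a summed count of 41 over 4 libraries, and 15754 genes for tumours, the smallest with 51 over 5 libraries. The deposited rlog tables hold log2 values of the same genes, shrunken by the authors, and were used only to describe the files. Each count table has 49671 genes, of which 49412 have a symbol in GENCODE M21, and no ERCC control is listed in them. The scaling by ERCC totals planned as an alternative was therefore not run. The column of the second KO tumour is numbered 3 while the labels number the KO tumours 1 and 2, so it was assigned to its group only.

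Total counts per library ran from 16032912 to 21247023. Counting intervals (95%, exact binomial on the split of counts between groups) and floors of 3 counts over a group cover counting error only, not the spread between replicates. Replicates of a group differed by more than counting noise, with a chi-square per gene from 6.58 to 44.2 between pairs, so no library is a copy of another. The 6.58 was that of WT tumours 1 and 2, against 25.4 or more in every other pair. These tumours were thus closer to each other than replicate cultures were. How independent they are cannot be told from the counts, and the tests treat the WT tumours as 3 independent samples.

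Genes were kept by filterByExpr (minimum count 10, minimum total count 15) within the libraries of each comparison, scaled by TMM, and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. KO was compared with WT within culture and within tumours, and the difference of the 2 effects was tested in 1 fit of all 9 libraries. The adjusted p is that of Benjamini and Hochberg over all genes tested in a comparison, with a threshold of 0.05. Printed log2 fold changes use edgeR's prior count of 0.125, the SE is the log2 fold change divided by the square root of F, and CPM are scaled by TMM within the comparison. Where a group has no count, only a bound is printed, and where it has 1 to 3 counts, the ratio of scaled counts with its interval. For genes named for the difference, ratios are those of scaled counts.

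The 42 gene lists were fixed before the data were examined and tested with camera of limma 3.58.1 at a preset correlation of 0.01, where at least 5 members passed the filter. Camera asks whether a list's genes are ranked higher or lower than other genes. It was repeated with the correlation estimated from the residuals, and fry was run beside it. A call lost with the estimate need not mean a higher correlation, as calls were also lost where the estimate lay below 0.01. Fry tests whether the genes of a list move, on balance, one way, and does not compare them with other genes. Member counts are given over all genes tested and adjusted over the list alone.

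The genes to be named were chosen by a rule written with the lists. It takes Itga2 first, then the 10 genes with the largest positive and the 10 with the largest negative log2 fold change (5 and 5 for the difference) among those that passed, had a mean CPM of at least 5 and, within a setting, had every KO library on the same side of every WT library. Gene models without a name of their own were passed over. From each list up to 4 members with the smallest p may be named, with Cd8a, Cd3e, Gzmb, Prf1, Ifng, Cxcl9, Cxcl10, Ccl5, Itgb1, Itga1 and Col1a1 wherever measured. Ltf in culture, and the members said to fall in lists of 7 or fewer, fall under the same rule.

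The alternatives were scaling by RLE or by library totals, no filter or a filter of CPM 1 in every library of a group, DESeq2 1.42.0, limma-voom, 1 fit of all libraries for the within-setting tests, the replicate number as a block, each library left out in turn, and a fold of at least 2. Restricting the difference to genes that pass the filter in both settings, and its block in culture only, were chosen after seeing the data. A count of calls within 1.5 times that reported was taken as the same.

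The tests were run on simulated data first, with counts drawn from the real means and library sizes and 200 genes changed, 50 at each of 4 log2 sizes. The changed genes had a mean of at least 5 CPM in each setting compared and lay outside the gene lists. Recovery of rarer genes, such as many T cell transcripts, was therefore not measured. In the culture design (13302 genes) edgeR recovered 100% at -2, 96% at -1, 98% at 1 and 100% at 2, and 6.67% of its calls were false. In the tumour design (15910 genes) it recovered 84%, 40%, 70% and 100% at those sizes, and 6.15% of calls were false, against 21.9% with DESeq2. For the difference (16413 genes) it recovered 90%, 32%, 20% and 96%, and 0.758% of calls were false. Camera found both of the 2 shifted lists in each design. Fry and camera with an estimated correlation found 0 of 2 in the culture design and 2 of 2 in the others, so in culture these can miss a shifted list. The simulated genes were drawn independently of each other. The simulation therefore cannot weigh the preset correlation against the estimated one where the genes of a list vary together.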

Results

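RNA was measured by bulk sequencing in a mouse pancreatic cancer cell line with intact CD49b (KPCWT, here WT) and its CD49b knockout counterpart (KPC49bKO, here KO). CD49b is integrin alpha 2, the product of Itga2, and pairs with the beta 1 chain to bind collagen. Both lines were sampled in culture (2 WT and 2 KO libraries) and as tumours grown under the skin of syngeneic mice and dissociated with enzymes (3 WT and 2 KO libraries). Each genotype is thus 1 line, and KO effect or effect of the knockout stands here for the difference between these 2 lines. The libraries cannot separate what is due to CD49b from other differences between the lines. The 2 KO tumours carry the numbers 1 and 3 in the data columns and are named by them here. Total counts lay between 17738774 and 21247023 in the 4 culture libraries and between 16032912 and 19562695 in the 5 tumour libraries. Fold changes are KO over WT on the log2 scale, and levels are CPM (counts scaled to a common library size) with the SD. Positions are those of GENCODE M21 on GRCm38, and each covers a whole gene.

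The targeted gene comes first. Itga2 (ENSMUSG00000015533, chromosome 13, 114833081 to 114932100, minus strand) stood at 144 and 113 CPM in the WT cultures and at 79.9 and 85.2 CPM in the KO cultures. In the tumours it stood at 139, 167 and 158 CPM in WT and at 51.8 and 72.4 CPM in KO. Itga2 thus fell in both settings, by 0.64 in culture (SE 0.17, edgeR adjusted p = 0.0135) and by 1.32 in tumours (SE 0.18, edgeR adjusted p = 0.00602). Every KO library lay below every WT library of its setting, so no library went against its label, but transcript remained in each. Counts per gene do not show whether the edited exon is present. The culture call was lost without WT culture 1 (edgeR adjusted p = 0.17) or without KO culture 1 (adjusted p = 0.11), and in 1 fit of all 9 libraries (adjusted p = 0.053).

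**Figure D1:**
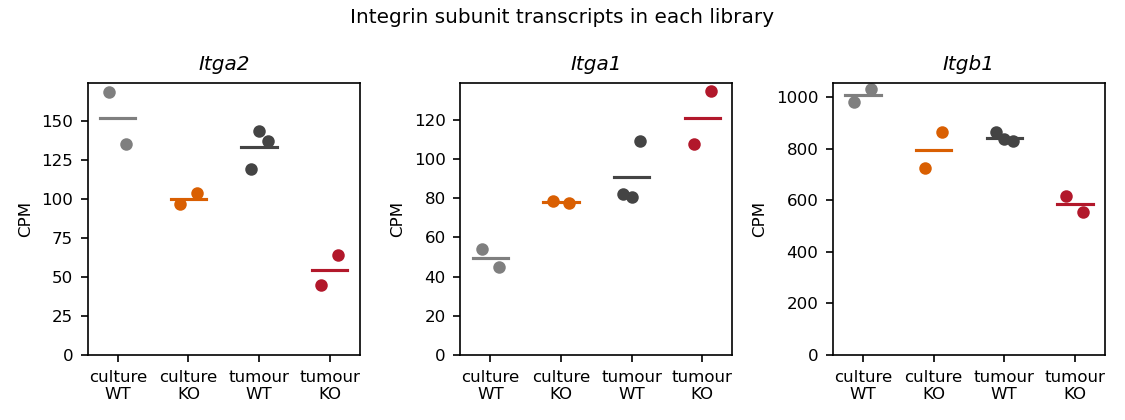
CPM of Itga2, Itga1 and Itgb1 in each of the 9 libraries, scaled over all 9 libraries together, so that levels differ slightly from those scaled within a setting; points are libraries and bars are group means. Every KO library lies below every WT library of its setting for Itga2 and Itgb1.

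The comparison of KO with WT cells in culture asks what differs between the lines without any host cells. Among the largest gains, Muc5ac, the gel-forming mucin of the stomach surface, rose from 0.162 ± 0.23 to 15.9 ± 5.07 CPM (SD, n = 2 and 2) with no count in WT culture 2, and Gkn2, a secreted protein of the stomach lining, rose from 1.2 ± 0.0897 to 22.8 ± 5.52 CPM. The largest losses took genes to nearly no counts in KO cells. Cldn7, a tight junction claudin, had 12.8 ± 2.68 CPM in WT and no count in either KO library, at least 168-fold lower. Of the measured genes of cholesterol synthesis 20 of 21 fell, as did 7 of 7 of the fibrillar collagens and matrix and 17 of 22 of the type I interferon response.

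In numbers, 3461 of 13573 genes tested passed the adjusted p threshold of 0.05 with edgeR, 1258 higher and 2203 lower in KO. The KO and WT libraries did not overlap for 61.4% of genes tested, against 33.3% by chance alone. Among the 10 largest gains, Muc5ac (chromosome 7, 141788972 to 141819231) rose by 6.55 (SE 0.53, edgeR adjusted p = 2.66e-06) and Bcas1 (chromosome 2, 170346991 to 170427845) by 5.44 (SE 0.25, adjusted p = 6.99e-08). Sox17, an endoderm transcription factor, rose by 2.53 from 29.8 ± 2.46 to 172 ± 19.6 CPM, and Ank, a membrane protein needed for the export of pyrophosphate, rose by 2.81 from 109 ± 0.371 to 766 ± 10.7 CPM. Mettl7b, Homer2, Pkhd1l1, Mucl3 and Fam71f1 completed the gains, with changes from 2.36 to 4.02. Among the 10 largest losses, Adcy1, an adenylyl cyclase, went from 17.6 ± 3.02 CPM in WT to 1 count in the KO libraries, a KO to WT ratio of 0.00145 (95% counting interval 3.66e-05 to 0.0081). For Nt5c3b the ratio was 0.00317 (counting interval 0.000653 to 0.00931), for Stmn2, a microtubule regulator of neurons, 0.00456 (0.00055 to 0.0166), and for Hook1 0.00577 (0.00119 to 0.017), each on 2 or 3 KO counts. Ckb, the brain-type creatine kinase, fell by 6.64 from 67.0 ± 7.07 to 0.681 ± 0.247 CPM, and Cadps, a factor for vesicle release, fell by 6.86 from 63.3 ± 4.29 to 0.555 ± 0.264 CPM. Ace, Cd300lb and Mab21l3 fell by 7.05 to 7.62.

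Of the 42 gene lists fixed in advance, 30 had enough members for a test in culture, and camera called 9, all lower in KO. None of the 9 calls held with an estimated correlation between genes in place of the preset one. For type I interferon, proliferation and macrophage genes the estimate was below the preset 0.01, at -0.041, -0.039 and -0.085. A higher correlation therefore did not end those calls. For the other called lists the estimate was above 0.01. In the simulated culture design the version with an estimated correlation found 0 of 2 shifted lists. Of 21 cholesterol synthesis genes 20 fell and 1 was not called (20 adjusted over the list alone), with a median of -1.58 (camera adjusted p = 1.05e-21, and adjusted p = 0.277 with an estimated correlation). They include Hmgcs1, an early enzyme of the pathway, down by 1.66 from 263 ± 11 to 83.2 ± 0.769 CPM, and Fdft1, squalene synthase, down by 2.25. All 7 measured fibrillar collagen and matrix genes fell (7 adjusted over the list alone), with a median of -3.64 (camera adjusted p = 1.3e-13, and adjusted p = 0.445 with an estimated correlation). Col6a1, a collagen VI chain, fell by 5.06 from 34.2 ± 2.26 to 1.02 ± 0.00936 CPM, and Fn1, fibronectin, by 2.36 from 197 ± 44.4 to 38.4 ± 6.44 CPM. Col1a1, the main chain of type I collagen, was rare even in WT cells (1.36 ± 0.911 CPM) and left 1 count in KO, a ratio of 0.0187 (counting interval 0.000464 to 0.109).

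Type I interferon response genes fell in culture, with 17 of 22 lower and 5 not called (18 lower and 1 higher adjusted over the list alone) and a median of -2.64 (camera adjusted p = 3.84e-11, and adjusted p = 0.277 with an estimated correlation). Oas1a, an antiviral RNA sensor, went from 13.4 ± 1.53 to 0.692 ± 0.392 CPM, and Ifih1, the sensor MDA5, from 5.61 ± 0.404 to 0.206 ± 0.031 CPM. In the MHC class I presentation list 8 of 20 fell, 2 rose and 10 were not called (9 and 2 adjusted over the list alone), with a median of -0.22 (camera adjusted p = 0.0215, and adjusted p = 0.511 with an estimated correlation), which ran from -0.12 without KO culture 1 to -0.48 without KO culture 2. The immunoproteasome genes Psmb8 and Psmb9 were among the fallers, at -4.35 and -4.02. Proliferation genes fell in 15 of 22 cases with 7 not called (18 adjusted over the list alone), with a median of -0.70 (camera adjusted p = 3.21e-05, and adjusted p = 0.369 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit, fell by 1.5 from 403 ± 23.8 to 142 ± 14 CPM.

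Of 15 mesenchymal transition genes 10 fell, 1 rose and 4 were not called (10 and 2 adjusted over the list alone), with a median of -1.80 (camera adjusted p = 9.94e-05, and adjusted p = 0.458 with an estimated correlation). S100a4 fell by 2.79 and Zeb2, a transcription factor that represses epithelial genes, by 3.33. Hypoxia and glycolysis genes had 8 lower, 1 higher and 12 not called of 21 (10 and 1 adjusted over the list alone), with a median of -0.32 (camera adjusted p = 0.0234, and adjusted p = 0.502 with an estimated correlation). The macrophage and monocyte list was tested on 7 members, of which 4 fell and 3 were not called (4 adjusted over the list alone), with a median of -1.12 (camera adjusted p = 0.0143, and adjusted p = 0.458 with an estimated correlation). Its fallers were Nos2, Spp1, Apoe and Cd68, which cancer cells can also express, and Spp1, osteopontin, went from 4064 ± 538 to 1290 ± 100 CPM. The call of Cd68 was lost with DESeq2 and without WT culture 1, WT culture 2 or KO culture 2. The dendritic cell list had 2 of 5 members lower and 3 not called (2 adjusted over the list alone), with a median of -0.94 (camera adjusted p = 0.0234, and adjusted p = 0.502 with an estimated correlation). Those members were Fscn1, an actin bundler, and Zbtb46, a transcription factor.

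Among collagen and laminin receptors, which camera did not call in culture (camera adjusted p = 0.632), 6 fell, 2 rose and 9 were not called (7 and 3 adjusted over the list alone). Cd44, a hyaluronan receptor, fell by 1.10 and Itga3, a laminin receptor chain, by 0.69. Itga1, another collagen-binding alpha chain, which lies next to Itga2 on chromosome 13, rose by 0.62 (SE 0.17, edgeR adjusted p = 0.0181) from 42.0 ± 6.19 to 64.3 ± 1.16 CPM. Itgb1, the shared beta 1 chain, was at 854 ± 20.4 in WT and 655 ± 76.1 CPM in KO (log2 fold change -0.38, edgeR adjusted p = 0.139). The calls for Itga1 were lost without WT culture 2, KO culture 1 or KO culture 2, those for the hypoxia and MHC class I lists without WT culture 2, and that for the dendritic list without WT culture 1. The share of counts from mitochondrial genes was 4.72% and 3.39% in the WT and 2.16% and 2.05% in the KO cultures, so it moved with the genotype.

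The comparison of KO with WT tumours addresses the question in the series title, whether CD49b on the cancer cells bears on the entry of CD8 T cells. In KO tumours Bcas1 rose by 7.08 (SE 0.37, edgeR adjusted p = 0.000487) from 2.07 ± 0.923 to 277 ± 72.1 CPM (SD, n = 3 and 2), and Alpi, intestinal alkaline phosphatase, rose by 5.84 (SE 0.35, edgeR adjusted p = 0.000763) from 9 ± 4.12 to 517 ± 52.4 CPM. Lgr5, a receptor that marks intestinal stem cells, was at 35.2 ± 19.2 CPM in WT tumours and had no count in KO tumours, at least 352-fold lower. Of 19 fibrillar collagen and matrix genes 16 fell, and of 20 oxidative phosphorylation genes 14 rose. The CD8 T cell transcript Cd8a stood at 7.56 ± 4.89 CPM in WT and 20.1 ± 8.85 CPM in KO and did not pass the test.

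In numbers, 3206 of 16257 genes tested passed with edgeR, 1428 higher and 1778 lower in KO. The KO and WT libraries did not overlap for 53.3% of genes, against 20% by chance alone. Muc5ac rose by 5.66, Mucl3 by 5.15 and Adh1, an alcohol dehydrogenase, by 5.72, while Capn13 rose by 5.08. Gkn2, Gkn1, Tff3 (a trefoil peptide of goblet cells) and Fam3b also passed, but their KO levels differed widely between the tumours. Gkn2 was at 360 ± 471 CPM in KO and 1.73 ± 1.49 CPM in WT, Gkn1 at 144 ± 193 and 2.59 ± 2.19, Tff3 at 23.7 ± 27 and 0.504 ± 0.371, and Fam3b at 16.5 ± 21 and 0.422 ± 0.139. Without WT tumour 1 all 4 of these calls were lost, and without KO tumour 1 the change in Gkn1 was 1.48 (edgeR adjusted p = 0.33) and that in Fam3b 1.92 (adjusted p = 0.097), while Gkn2 and Tff3 kept their calls at 3.90 and 3.22. All 4 calls were also lost with limma-voom. Leaving out WT tumour 2 ended the calls of Gkn2, Gkn1 and Fam3b, and leaving out WT tumour 3 those of Gkn1, Tff3 and Fam3b.

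Among the losses, Spock3, a matrix proteoglycan (chromosome 8, 62951009 to 63357103), had 55.0 ± 5.58 CPM in WT tumours and no count in KO, at least 567-fold lower. Map3k21 was at least 379-fold lower, Rassf10 at least 161-fold, and Grem1, a secreted antagonist of bone morphogenetic proteins, at least 129-fold. Olfm4, a marker of intestinal stem cells, and Cpne4 were each at least 104-fold lower, and Kcns3, a potassium channel subunit, at least 84.1-fold. Auts2 went from 42.8 ± 19.1 CPM to 2 counts, a ratio of 0.00154 (counting interval 0.000187 to 0.00558). Fgfr4, a fibroblast growth factor receptor, fell by 8.28 (SE 0.39, edgeR adjusted p = 0.000487) from 81.8 ± 9.37 to 0.248 ± 0.254 CPM.

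All 42 lists were tested in tumours and camera called 16, of which 9 were higher and 7 lower in KO. None held with an estimated correlation. For collagen and laminin receptors that estimate, -0.044, was below the preset 0.01, and for the other called lists it was above. Of 19 fibrillar collagen and matrix genes 16 fell and 3 were not called (19 adjusted over the list alone), with a median of -1.996 (camera adjusted p = 1.99e-11, and adjusted p = 0.697 with an estimated correlation). Col12a1 fell by 3.16 from 134 ± 45.3 to 14.9 ± 3.24 CPM, and Thbs2, a matricellular thrombospondin, by 3.19 from 111 ± 46.5 to 12.1 ± 8.09 CPM. Col1a1 fell by 1.97 (SE 0.44, edgeR adjusted p = 0.0253) from 1046 ± 519 to 267 ± 90.1 CPM, a call lost without WT tumour 1 or KO tumour 1. Camera called neither of the 2 lists of stromal cell markers. Fibroblast and pericyte markers had 3 of 18 lower, 1 higher and 14 not called (3 and 1 adjusted over the list alone), with 14 of 18 below 0 and a median of -0.61 (camera adjusted p = 0.163). Endothelial markers had 3 of 21 lower, 1 higher and 17 not called (3 and 1 adjusted over the list alone), with 19 of 21 below 0 and a median of -0.74 (camera adjusted p = 0.131). In the basement membrane list 6 of 18 fell, 2 rose and 10 were not called (10 and 3 adjusted over the list alone), with a median of -0.62 (camera adjusted p = 0.00257, and adjusted p = 0.697 with an estimated correlation), or -0.34 without KO tumour 1 and -1.01 without KO tumour 3. Col7a1, the collagen of anchoring fibrils, fell by 4.04 from 65.1 ± 10.6 to 3.97 ± 1.21 CPM and Lamb1, a laminin chain, by 2.36.

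Collagen and laminin receptors fell in 8 of 19 cases, with 1 higher and 10 not called (8 and 1 adjusted over the list alone) and a median of -0.54 (camera adjusted p = 0.00707, and adjusted p = 0.697 with an estimated correlation). Itga5, the alpha chain of the fibronectin receptor, fell by 1.86 from 102 ± 13.1 to 28.2 ± 7.79 CPM, and Itga3 by 1.15 from 486 ± 31.8 to 220 ± 6.01 CPM. Itgb1 fell by 0.54 (SE 0.12, edgeR adjusted p = 0.0266), a call lost without WT tumour 1, WT tumour 2 or KO tumour 3, and Itga1 stood at 105 ± 18.4 in WT and 138 ± 19 CPM in KO (log2 fold change 0.40, adjusted p = 0.152). Mesenchymal transition genes had 9 of 20 lower, 1 higher and 10 not called (11 and 1 adjusted over the list alone), with a median of -1.20 (camera adjusted p = 0.00176, and adjusted p = 0.869 with an estimated correlation). Twist1, a transcription factor of that programme, fell by 3.12 and S100a4 by 2.75. Matrix proteases and crosslinkers had 7 of 22 lower, 2 higher and 13 not called (12 and 2 adjusted over the list alone), with a median of -0.88 (camera adjusted p = 0.0204, and adjusted p = 0.697 with an estimated correlation). Mmp9, a gelatinase, fell by 3.38 while Mmp15, a membrane-bound protease, rose by 3.89 from 24.3 ± 7.95 to 358 ± 60.1 CPM. YAP and TEAD targets had 6 of 18 lower and 12 not called (6 adjusted over the list alone), with a median of -0.16 (camera adjusted p = 0.00697, and adjusted p = 0.697 with an estimated correlation), and included Ccn2, a matricellular growth factor, down by 2.06 from 278 ± 49.7 to 66.7 ± 19 CPM. The median of that list was -0.06 without WT tumour 3, -0.29 without WT tumour 1, -0.32 without KO tumour 1 and -0.37 without KO tumour 3.

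Classical pancreatic cancer genes, which mark the gland-like subtype, rose in 10 of 18 cases with 8 not called (11 adjusted over the list alone), with a median of 0.87 (camera adjusted p = 1.94e-07, and adjusted p = 0.697 with an estimated correlation). Tff1, a trefoil peptide of the stomach, rose by 4.19 from 122 ± 34.9 to 2223 ± 1458 CPM and Tff2 by 2.93 from 63.6 ± 21.8 to 484 ± 85.3 CPM. Oxidative phosphorylation genes rose in 14 of 20 cases with 6 not called (18 adjusted over the list alone), with a median of 0.81 (camera adjusted p = 6.28e-08, and adjusted p = 0.869 with an estimated correlation). Uqcrc2, a subunit of respiratory complex III, rose by 0.85 from 102 ± 1.52 to 184 ± 18.4 CPM. The share of counts from mitochondrial genes was 1.90%, 2.00% and 1.93% in WT tumours and 3.33% and 2.69% in KO tumours, so it moved with this list.

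**Figure D2:**
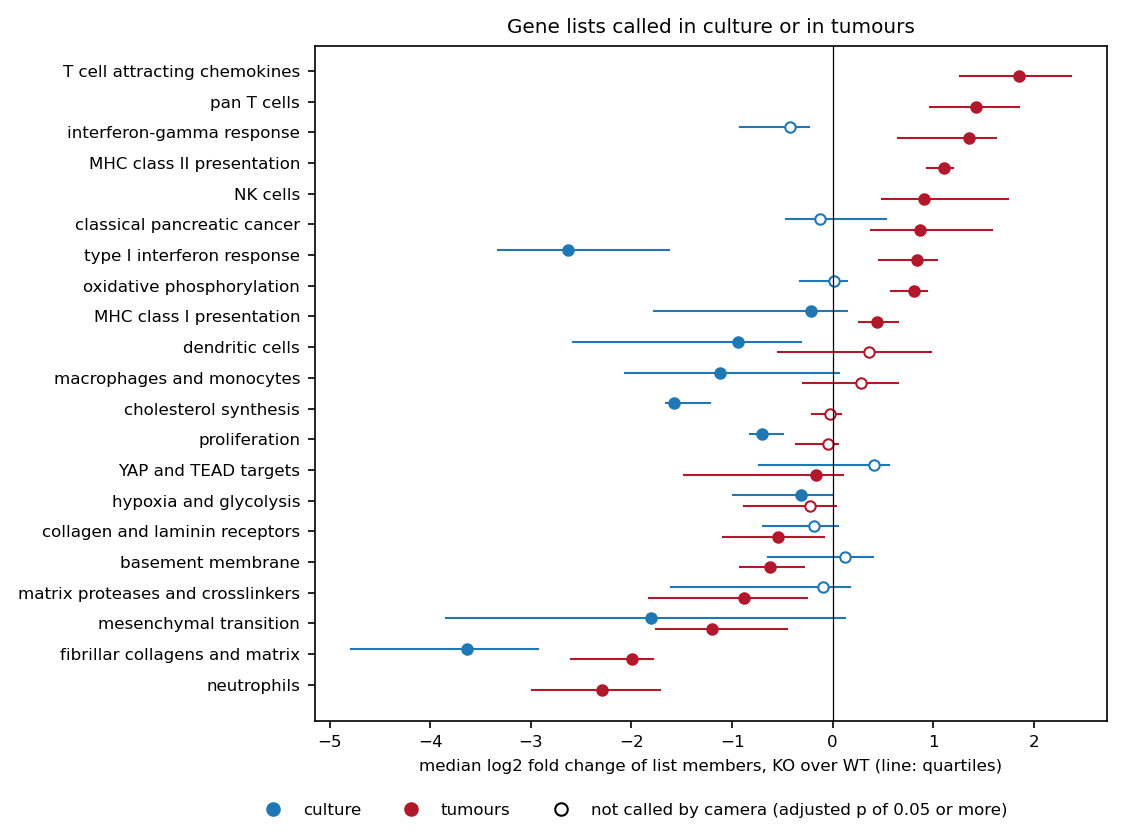
Median log2 fold change, KO over WT, of the members of each gene list called in culture or in tumours, with lines from the lower to the upper quartile; filled points passed camera with the preset correlation and open points did not. Type I interferon genes have a median of -2.64 in culture and 0.84 in tumours, and fibrillar collagens lie below 0 in both.

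T cell transcripts were at low levels in all tumours. Of the genes fixed in advance, Cd3e, a T cell receptor chain, was at 1.69 ± 1.37 CPM in WT and 6.38 ± 3.07 CPM in KO (log2 fold change 1.92, edgeR adjusted p = 0.128, or 0.04 without a filter). Cd8a had a log2 fold change of 1.42 (SE 0.66, edgeR adjusted p = 0.174), and the killing proteins Gzmb and Prf1 had 0.07 (adjusted p = 0.968) and 0.91 (adjusted p = 0.356). The chemokine Ccl5, which draws T cells, rose by 2.60 (SE 0.43, edgeR adjusted p = 0.0106) from 0.895 ± 0.305 to 5.45 ± 2.23 CPM, a call lost without WT tumour 2. For Cxcl9 the log2 fold change was 2.09 (edgeR adjusted p = 0.115) and for Cxcl10 1.46 (adjusted p = 0.187), and both were called without KO tumour 1 (adjusted p = 0.025 and 0.014), and Cxcl9 also without a filter and in 1 fit of all libraries. Without KO tumour 3 the log2 fold change was 0.89 for Cd8a, -0.03 for Cxcl9, -0.54 for Cxcl10, -2.07 for Gzmb and -0.18 for Prf1, none of them called. Ifng had too few counts to pass the filter. In the list of CD8 T and cytotoxic cell markers 2 of 13 rose, 1 fell and 10 were not called (2 and 1 adjusted over the list alone), and camera did not call it (median 1.42, camera adjusted p = 0.158). Cd8b1 rose by 2.72, Ctsw by 1.81 and Gzmc fell by 2.84, and leaving out any of 4 of the 5 tumours ended each of those calls. Without KO tumour 1 the CD8 list was called (median 1.99, camera adjusted p = 0.0022), while the list of all 5 tumours, with an estimated correlation, was not (camera adjusted p = 0.89).

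Other lists of immune cells and interferon responses were called by camera, and each lost its call on leaving out KO tumour 3 or WT tumour 3. These fits also have fewer samples. Leaving out WT tumour 1 or WT tumour 2 instead gave 20 and 18 called lists against 16, so the number of called lists need not fall with fewer samples. The number of called genes did fall, from 3206 to 1258 and 1171. WT tumours 1 and 2 were also the most alike pair (chi-square per gene 6.58). Leaving out 1 of them is thus a weak control for leaving out KO tumour 3 or WT tumour 3. Pan T cell markers had 1 of 19 higher (Trbc1, at 2.99, a call lost without WT tumour 2 or KO tumour 1), 1 lower and 17 not called (1 and 1 adjusted over the list alone), with a median of 1.43 (adjusted p = 0.0179, and adjusted p = 0.89 with an estimated correlation). The faller was Bcl11b, a transcription factor of T cells that other tissues also express, from 30 ± 8.36 to 6.01 ± 2.64 CPM. T cell attracting chemokines had 2 of 8 higher and 6 not called (4 adjusted over the list alone), with a median of 1.85 (adjusted p = 0.00847, and adjusted p = 0.697 with an estimated correlation). NK cell markers had 1 of 11 higher (Klrc1, at 0.76, a call lost on leaving out any tumour) and 10 not called (4 adjusted over the list alone), with a median of 0.91 (adjusted p = 0.0379, and adjusted p = 0.89 with an estimated correlation). Klrc1 and Klra4 are not limited to NK cells here, as the cultures, which hold no host cells, had 11.5 ± 1.62 CPM of Klrc1 in WT and 3.85 ± 0.363 in KO, and 24.3 ± 4.3 and 11 ± 0.25 CPM of Klra4. Neutrophil markers had 4 of 12 lower and 8 not called (4 adjusted over the list alone), with a median of -2.30 (adjusted p = 0.00779, and adjusted p = 0.89 with an estimated correlation). Ltf, lactoferrin, fell by 5.51 from 24.9 ± 12.3 to 0.526 ± 0.551 CPM. It also fell in culture, where no neutrophils are present, to a KO to WT ratio of 0.0655 (counting interval 0.0548 to 0.0777).

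Type I interferon genes rose in 11 of 26 cases with 15 not called (16 adjusted over the list alone), with a median of 0.84 (camera adjusted p = 3.06e-06, and adjusted p = 0.869 with an estimated correlation). Stat2, a signal transducer of the interferon receptor, rose by 1.11 from 54.5 ± 3.55 to 118 ± 16.8 CPM. Interferon-gamma response genes had 3 of 22 higher and 19 not called (1 adjusted over the list alone), with a median of 1.35 (adjusted p = 0.00779, and adjusted p = 0.89 with an estimated correlation). Ido1, an enzyme that breaks down tryptophan, was at 2.54 ± 1.77 CPM in WT and 42.8 ± 38.9 CPM in KO, and its call was lost without WT tumour 1, WT tumour 2 or KO tumour 3. MHC class I presentation genes had 5 of 22 higher and 17 not called (6 higher and 1 lower adjusted over the list alone), with a median of 0.44 (adjusted p = 0.00779, and adjusted p = 0.89 with an estimated correlation). B2m, the light chain of MHC class I, rose by 1.5 from 585 ± 161 to 1658 ± 433 CPM. MHC class II presentation genes had 2 of 9 higher and 7 not called (2 adjusted over the list alone), with a median of 1.10 (adjusted p = 0.0341, and adjusted p = 0.89 with an estimated correlation). Without KO tumour 3 the interferon-gamma median was -0.31 (camera adjusted p = 0.893), and the YAP list was no longer called at -0.37. The type I interferon (median 0.43, camera adjusted p = 0.062), MHC class I (0.14), MHC class II (0.04), T cell chemokine (0.56), pan T (0.69) and NK (0.35) lists also lost their calls, each with a smaller median. Without WT tumour 3 the interferon-gamma (median 1.11), MHC class I (0.28), MHC class II (0.98), pan T (1.14), NK (0.66), neutrophil (-0.51) and matrix protease (-0.86) lists were no longer called, and the stricter filter ended the MHC class II call (adjusted p = 0.067 with camera).

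**Figure D3:**
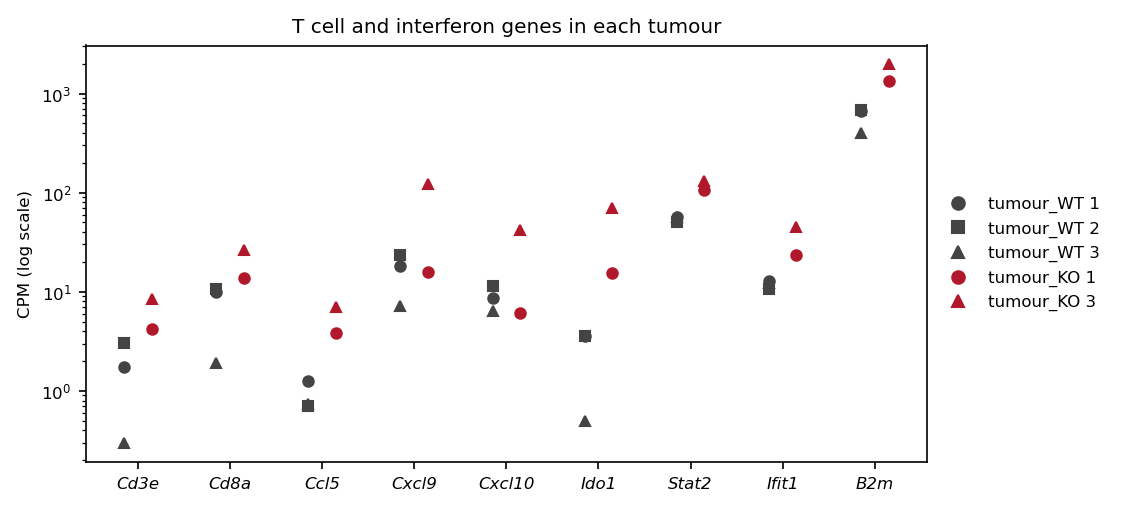
CPM on a log scale of T cell, chemokine and interferon genes in each tumour, with marker shapes for the library number and colours for the genotype. KO tumour 3 has the higher level of the KO pair for Cd8a, Cxcl9, Cxcl10 and Ido1.

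The settings were then compared directly, by testing whether the KO effect differed between tumours and culture. Of 26 type I interferon genes 18 had a more positive effect in tumours than in culture. Ifih1, for example, had a KO to WT ratio of 0.0374 in culture (counting interval 0.0159 to 0.075) and of 1.22 in tumours (1.12 to 1.33). The same held for 17 of 21 cholesterol synthesis genes, among them Fdft1 at ratios of 0.217 and 1.06. Tff3 moved in opposite directions, from 19.6 ± 8.22 in WT to 3.06 ± 0.785 CPM in KO cultures and from 0.434 ± 0.321 to 20.5 ± 23.1 CPM in tumours. Lcn2, lipocalin 2, which binds bacterial iron carriers, did the reverse, with 18.3 ± 2.39 in WT and 33.0 ± 4.62 CPM in KO cultures and 25.1 ± 19.2 and 0.844 ± 0.0463 CPM in tumours.

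The KO effect differed for 955 of 16793 genes tested with edgeR, 697 with a more positive and 258 with a more negative effect in tumours. By edgeR's estimates, the largest positive differences among the genes open to naming were in Gng2, Tm4sf5, Slfn5, Tff3 and Trp53i11. All but Tff3 had no count in KO cultures, so their estimates and their rank rest on the prior count. In KO cultures Gng2, a G protein subunit, was at least 63.8-fold lower than in WT, Trp53i11 at least 40.9-fold, Slfn5 at least 17.7-fold and Tm4sf5 at least 2.77-fold. The KO to WT ratios of these genes in tumours were 0.503, 0.535, 1.48 and 10.7. The largest negative differences were in Lcn2 (-5.74, SE 0.99, edgeR adjusted p = 0.00831), Aqp5 (-5.16), B4galnt2 (-4.76), Fgfr4 (-4.72) and Cxcl3 (-4.64, adjusted p = 0.0201). Aqp5, a water channel, went from 11.7 ± 0.136 to 35.0 ± 1.42 CPM in culture and from 1.40 ± 0.6 to 0.113 ± 0.00618 CPM in tumours. Cxcl3, a chemokine for neutrophils, went from 81.9 ± 10 to 237 ± 17.9 CPM in culture and from 11.1 ± 10.9 to 1.28 ± 0.406 CPM in tumours. The call of Cxcl3 was lost on leaving out any of the culture libraries, that of Lcn2 without WT culture 2, and both with limma-voom. For Itga2 the effect did not differ between settings (-0.70, edgeR adjusted p = 0.15), and it did without KO tumour 3 (-0.97, adjusted p = 0.029).

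Camera called 13 of 42 lists for the difference, 8 with a more positive and 5 with a more negative effect in tumours, and none held with an estimated correlation. For type I interferon genes 18 of 26 differed upward and 8 were not called (24 adjusted over the list alone), with a median of 3.07 (adjusted p = 6.09e-37, and adjusted p = 0.227 with an estimated correlation). For cholesterol synthesis 17 of 21 differed upward and 4 were not called (18 adjusted over the list alone), with a median of 1.43 (adjusted p = 1.84e-25, and adjusted p = 0.227 with an estimated correlation). Classical pancreatic cancer genes had 6 of 18 upward and 12 not called (10 adjusted over the list alone), with a median of 1.23 (adjusted p = 2.72e-07, and adjusted p = 0.227 with an estimated correlation). Ctse, cathepsin E, is an example, with ratios of 0.522 in culture and 3.11 in tumours. Oxidative phosphorylation genes had 7 of 20 upward and 13 not called (16 adjusted over the list alone), with a median of 0.85 (adjusted p = 5.91e-09, and adjusted p = 0.571 with an estimated correlation). MHC class I presentation genes had 5 of 22 upward and 17 not called (12 adjusted over the list alone), with a median of 1.08 (adjusted p = 4.09e-09, and adjusted p = 0.557 with an estimated correlation). Epithelial identity genes had 5 of 17 upward and 12 not called (5 adjusted over the list alone), with a median of 0.77 (adjusted p = 9.46e-05, and adjusted p = 0.546 with an estimated correlation). Krt19, a keratin of duct cells, had ratios of 0.743 and 2.07.

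Interferon-gamma response genes had 2 of 22 upward and 20 not called (4 adjusted over the list alone), with a median of 1.31 (adjusted p = 0.0144, and adjusted p = 0.952 with an estimated correlation). NK cell markers had 2 of 11 upward and 9 not called (3 adjusted over the list alone), with a median of 2.12 (adjusted p = 0.0321, and adjusted p = 0.699 with an estimated correlation). As 8 of these 11 had no count in at least 1 group, that median rests largely on the prior count, and the call says little about the KO effect in culture. YAP and TEAD targets had 3 of 18 downward, 1 upward and 14 not called (7 and 1 adjusted over the list alone), with a median of -0.52 (adjusted p = 0.000322, and adjusted p = 0.558 with an estimated correlation). MAPK feedback targets had 4 of 20 downward and 16 not called (4 adjusted over the list alone), with a median of -0.18 (adjusted p = 0.00413, and adjusted p = 0.571 with an estimated correlation), which ran from -0.03 without KO culture 1 to -0.32 without KO culture 2. Egr1, an immediate early transcription factor, had ratios of 3.51 in culture and 0.447 in tumours. Basement membrane genes had 2 of 18 downward, 1 upward and 15 not called (3 and 1 adjusted over the list alone), with a median of -0.64 (adjusted p = 0.0144, and adjusted p = 0.69 with an estimated correlation). NF-kB targets had 2 of 20 downward, 1 upward and 17 not called (3 and 1 adjusted over the list alone), with a median of -0.23 (adjusted p = 0.02, and adjusted p = 0.699 with an estimated correlation). Collagen and laminin receptors had 1 of 19 downward and 18 not called (2 adjusted over the list alone), with a median of -0.24 (adjusted p = 0.03, and adjusted p = 0.422 with an estimated correlation). Without KO tumour 3 the interferon-gamma (median 0.33, camera adjusted p = 0.62), NK and basement membrane calls were lost, and without KO tumour 1 those of basement membrane, NF-kB and receptors. WT culture 2 and KO culture 1 each ended the calls of NK, basement membrane, NF-kB and receptor genes when left out, WT culture 1 that of the receptors, and WT tumour 3 that of interferon-gamma.

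Many KO effects were shared between culture and tumours. The same KO line and the same WT line were used in both settings. Any lasting difference between them, related to CD49b or not, would thus be shared. Muc5ac, Bcas1, Gkn2 and Mucl3 were among the 10 largest gains in both settings, and Nt5c3b, Ckb and Cadps fell in both. Of 13147 genes tested in both, 428 were higher in KO in each setting against 123 by chance (Fisher's exact test, 1-sided, p = 3.31e-142), and 748 were lower against 222 (p = 1.36e-271). Another 26 genes rose in culture and fell in tumours, and 93 did the opposite. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.61 and a Spearman correlation of 0.44.

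**Figure D4:**
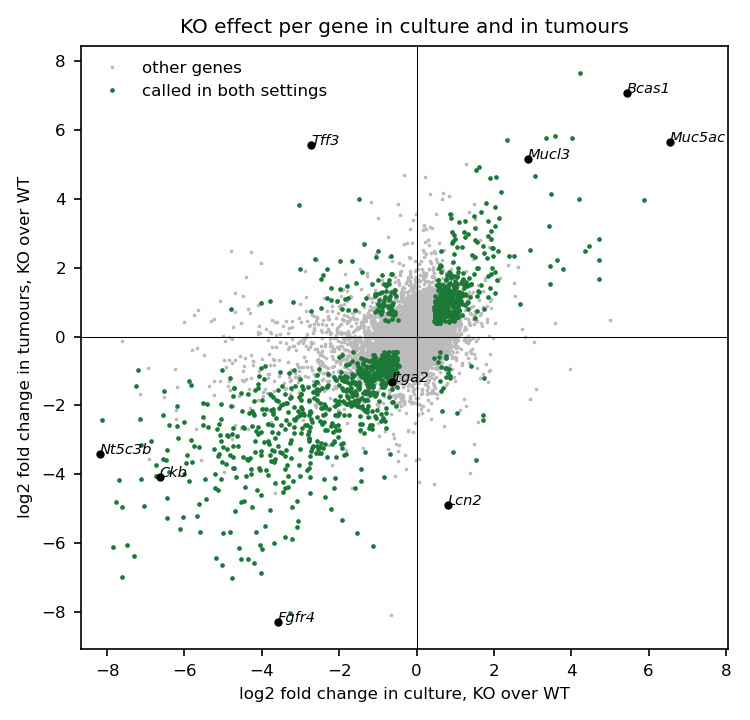
Log2 fold change, KO over WT, in culture against that in tumours for each gene tested in both settings, without genes that have no count in a group; green points passed the test in both. Bcas1, Muc5ac and Mucl3 lie high in both settings, Ckb, Nt5c3b and Fgfr4 low in both, and Tff3 and Lcn2 on opposite sides of 0.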

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

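The test of the difference between tumours and culture was planned, while the patterns weighed below were chosen after their results were seen. Each result here stands out because the effect of the knockout differed between the settings by that test (edgeR for genes, camera for lists). In all, 955 genes differed. Over the members counted in every group, the median log2 difference (tumours minus culture) was 3.07 for type I interferon response, 1.43 for cholesterol synthesis, 1.08 for MHC class I presentation, 0.85 for oxidative phosphorylation and 1.23 for classical pancreatic cancer genes. It was 0.71 for epithelial identity, 1.54 for interferon-gamma response and, over only 3 of 11 members, 2.32 for NK cell markers. It was -0.52 for YAP and TEAD targets, -0.18 for MAPK feedback targets, -0.43 for basement membrane, -0.23 for NF-kB targets and -0.19 for collagen and laminin receptors. None of these lists held with an estimated correlation, where the smallest camera adjusted p was 0.227.

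Among named genes, the log2 difference was 8.24 for Tff3, 4.77 for Nt5c3b, 3.96 for Cd300lb, 3.80 for Cadps, 2.55 for Ckb and 2.25 for Mucl3. It was -2.85 for Ank, -5.16 for Aqp5, -4.76 for B4galnt2, -4.64 for Cxcl3, -4.72 for Fgfr4 and -5.74 for Lcn2. Nt5c3b, Cd300lb, Cadps and Ckb fell in both settings, with -3.42, -3.15, -3.03 and -4.07 in tumours, so their difference is a smaller fall there. Ckb was at 0.681 CPM in KO cultures and 5.45 in KO tumours. Cadps was at 63.3 CPM in WT cultures and 6.59 in WT tumours. What host cell RNA in the tumours adds to such differences was not tested. For genes with no count in KO cultures only the edgeR adjusted p of the difference is given, 0.00909 for Cldn7, 0.00296 for Gng2, 0.0224 for Slfn5, 0.0379 for Tm4sf5 and 0.00366 for Trp53i11.

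Type I interferon genes were lower in KO cultures and higher in KO tumours, and all tests of this pattern were written after it was seen. A fall limited to members under a WT CPM of 5 was excluded, as the 13 members at 5 or more in culture had a median of -1.97. Their upper quartile was -0.21. Of these 13, 8 were called lower, from WT levels between 5.24 (Rtp4) and 13.4 CPM (Oas1a). The 5 members not called lower had a WT CPM of 13.3 or more. The calls thus lay mostly at the lower levels, and a fall that depends on the level stays open. An earlier split on the mean of WT and KO was dropped after its result was seen, because the fall itself moves members under it. Scaling was excluded, as the lowest tumour median under the other scalings was 0.7647, whereas more leukocyte RNA in KO tumours could not be told apart (macrophage and monocyte median 0.286, upper quartile 0.65, against a lower quartile of 0.46 for the interferon list). The rise in tumours was smaller without KO tumour 3 (median 0.43, camera adjusted p = 0.062) than without KO tumour 1 (median 1.09), and a biological reading, such as signals from host cells acting on KO cancer cells, remains an untested hypothesis.

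Most genes at least 16-fold lower in KO cultures were also lower in KO tumours, a pattern found after the culture result was seen; the predictions on chromosomes were written before their tests and that on tumours after. There were 94 such genes, against 7 by the reverse rule. They were called lower and had a WT mean of 5 CPM or more. Their KO mean was at or under 1/16 of that, and up to 6.07 CPM. Of 93 tested in tumours 68 were called lower and 0 higher, while 10 lay above 0. The 93 had a median of -3.03 and an upper quartile of -1.44, which excluded a state of the culture plates as the cause of most of these falls. The 10 above 0 included the type I interferon genes Ifih1, Oas1a, Oas3 and Rtp4 and the immunoproteasome genes Psmb8 and Psmb9. For those 10 such a state stays open. As a cause of most of these falls, loss of segments spanning several expressed genes was excluded. Only 4.255% had an immediate neighbour among expressed genes with such a fall too (4 genes, with a median of 2 in 10000 random placements). A loss that covers a single expressed gene cannot be seen this way. For loss of whole chromosomes, the 2 richest chromosomes held 21.28%. That share cannot decide it, because losing 1 copy of a chromosome would not lower a gene 16-fold. Copy number differences between the lines stay open, because no DNA was measured. Chromosomes 15, 11 and 16 had gene medians of -0.25, -0.23 and -0.18 in culture and of -0.425, -0.35 and -0.32 in tumours. Chromosome 12 had -0.18 and 0.01. That the KO line stems from a single cell with its own set of low genes, unrelated to CD49b, is a hypothesis that these data cannot test, since the labels name 1 KO line.

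Oxidative phosphorylation genes were higher in KO tumours, a pattern chosen for weighing after it was seen, with the length test predicted before it was run and the test on single tumours after. Values argued against transcript length as the whole cause. The list's median of 0.81 lay at percentile 100 of 10000 random lists matched on exon length and CPM, whose own median was 0.20. A part of the rise that follows length stays open. The matched genes were drawn independently, while the genes of this list vary together (estimated correlation 0.81), so the percentile overstates how far the list stands out. A rise carried by 1 KO tumour alone was excluded, as the lower of the medians without 1 KO tumour was 0.5767. That was the median without KO tumour 1, against 0.949 without KO tumour 3. With only 2 KO tumours, whether 1 of them is aberrant cannot be decided. Ribosomal protein genes, another set of short abundant transcripts, had a median of 0.35 with 17 of 75 higher and 0 lower, and the share of mitochondrial counts was also higher in both KO tumours. A change in the metabolism of KO tumour cells and a different mix of cells in the tumours were not told apart.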

How the results depend on the processing

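No call for a gene turned direction under any alternative. Scaling, filters and tools left the numbers of calls in culture (3039 to 3636) and in tumours (2942 to 4178) within 1.5 times those reported, as did 1 fit of all libraries (2900 and 4089), and the difference grew to 1875 (1308 higher, 567 lower) without a filter and to 1615 (1060, 555) with DESeq2, for which the cause was not tested. A fold of at least 2 left 1776 calls in culture (300 higher) and 1832 in tumours (619 higher) by construction. With an estimated correlation camera called 0 lists in culture, 0 in tumours and 0 for the difference. Fry called 10, 4 and 3, of which camera at the preset correlation called 7, 2 and 3 in the same direction. In tumours fry did not call fibrillar collagens and matrix (fry adjusted p = 0.124), oxidative phosphorylation (0.138) or type I interferon genes (0.183). In culture fry called epithelial identity lower (fry adjusted p = 0.000248), which camera did not call (camera adjusted p = 0.0883). Leaving out 1 library, with lone samples assumed to vary like the other groups, gave 2130 to 2985 calls in culture (570 to 986 higher, 1560 to 1999 lower), 1171 to 4143 in tumours (417 to 2154 higher, 754 to 1989 lower) and 288 to 1651 for the difference (232 to 1148 higher, 44 to 503 lower). It gave 8 to 11 lists in culture, 10 to 22 in tumours and 10 to 16 for the difference, and 189 to 478 shared higher and 414 to 824 shared lower genes. The interferon-gamma list in tumours ran from a reversed median of -0.31 without KO tumour 3 to 2.12 without KO tumour 1, and fewer samples are part of that alternative. Of the calls reported, a left-out library kept 58.1% to 73.9% in culture, 36.3% to 81.9% in tumours and 29.7% to 91.9% for the difference.

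Replicate numbers were not taken to pair the samples, since no label says what a number shares and culture has only 2 pairs. Deviations of same-numbered cultures correlated at 0.403 and those of the other pairs at -0.403. With 2 libraries per group the equal size and opposite sign are fixed by construction, but the size is not. Pairing in culture therefore stays open. With the replicate block, which leaves 1 residual degree of freedom, culture had 7587 calls (3689 higher, 3898 lower). The block by column number gave 1428 in tumours (485 higher, 943 lower) and 546 for the difference (396, 150), against 1100 with the block in culture only, an addition made after results were seen. In tumours it uses the 3 of a KO column, a number that no KO tumour label has, leaves 1 residual degree of freedom, and was left out at first after its counts were seen. Deviations of same-numbered tumours correlated at -0.00149 and 0.0399, so the lost calls do not speak for a weaker effect. The scaling by ERCC totals was not run because the count tables list no ERCC control.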

Other observations

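The genes in these paragraphs were chosen after their values were seen, and all CPM are scaled over the 9 libraries together. Cdkn2a and Cdkn2b, neighbouring cell cycle inhibitor genes on chromosome 4, were at similar levels in all cultures, with 154 ± 22.4 and 86.7 ± 9.28 CPM in WT and 156 ± 4.89 and 103 ± 11.8 CPM in KO (SD, n = 2 and 2). In WT tumours they were at 3.93 ± 0.563 and 2.70 ± 0.415 CPM (n = 3). In KO tumours Cdkn2a was at 76.2 and 17.8 CPM and Cdkn2b at 42.0 and 8.92 CPM. Cdkn2a was higher in KO tumours (log2 fold change 3.57, edgeR adjusted p = 0.00964), as was Cdkn2b (3.23, edgeR adjusted p = 0.0151). Mtap, the next gene and an enzyme of methionine salvage, was at 315 ± 9.36 CPM in WT cultures, 119 ± 24.1 in WT tumours and 109 ± 39.4 in KO tumours.

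Vsig1, an adhesion protein of gastric epithelium, was higher in KO than in WT in both settings. It went from 85.2 ± 9.11 to 203 ± 4.8 CPM in culture (edgeR adjusted p = 0.000117). In tumours it went from 131 ± 16 to 474 ± 28.8 CPM (edgeR adjusted p = 0.00129). Anxa10 did not pass in culture (log2 fold change -0.18, edgeR adjusted p = 0.537) and rose in tumours from 165 ± 33.2 to 418 ± 58.9 CPM (edgeR adjusted p = 0.00777). Dclk1, a kinase that marks tuft cells, was at 80.1 ± 21.1 CPM in WT tumours and 0.498 ± 0.29 CPM in KO tumours (log2 fold change -7.31, edgeR adjusted p = 0.000538), and WT cultures had 0.417 ± 0.0357 CPM. Epcam, an epithelial adhesion protein, was at 3.50 ± 0.0549 CPM in WT cultures and left 1 count in KO cultures, a ratio of 0.00857 (95% counting interval 0.000215 to 0.0488), and fell in tumours from 110 ± 44.8 to 37.6 ± 4.72 CPM (edgeR adjusted p = 0.0243). Cdh1, E-cadherin, rose in culture from 703 ± 57 to 1110 ± 22.4 CPM (edgeR adjusted p = 0.0215) and did not pass in tumours (log2 fold change 0.29, edgeR adjusted p = 0.213).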
